A study of Mus musculus with 40 samples.

How the data were processed

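The authors sequenced RNA, immunoprecipitated chromatin, input DNA and accessible chromatin of mouse spleen CD4 T cells on the C57BL/6 background, and deposited 1 table of gene values and 13 peak lists. Per the labels, naive cells were cultured with anti-CD3 (10 ug/mL), anti-CD28 (1 ug/mL), IL-4 (50 ng/mL) and anti-IFN-gamma for Th2 cells, with IL-2 at 30 IU/mL from day 3, and part of the cells was moved on day 6 to IL-12 (10 ng/mL) with anti-IL-4. The submitters' processing notes name cutadapt 1.3, BWA 0.7.10, TopHat2 2.0.5, DESeq, MACS2 2.1.0 and the mm10 genome. The gene annotation used for counting is not given in the sources used here.

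The signal values of the RNA table were made by the authors as read counts per gene divided by a size factor per library. Whole reads could be recovered from 100% of values within 0.01, and the factors equalled medians of ratios over the 11929 genes present in all libraries. The deposited file held each gene in 2 identical copies, and the first copy of 39179 genes was used. The score values of the peak lists are the authors' own: in the MACS2 layout they are 10 times the -log10 q, and in the H3K9me3 lists the caller and the scale are not given in the sources used here. The ratio values, given by the authors as fold enrichment over local background in the MACS2 layout, were not used. The -log10 p values, deposited by the authors in the same layout as the caller's own test of each peak, were not used either. Scores served only to keep, as an alternative, the peaks at or above the median score of a list.

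RNA was tested with limma 3.58.1 (trend) on the log2 of the deposited value plus 1. All 18 libraries were in 1 fit with 1 coefficient per group, which left 12 residual degrees of freedom, and p was adjusted by Benjamini-Hochberg with a threshold of 0.05. Genes with a value of at least 10 in at least 2 libraries were kept, 17254 in all. Whether an effect differed between conditions was tested as an interaction in the same fit. The recovered reads were tested with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 as alternatives. Groups with no read were compared with a floor of 3 reads per library, which covers counting error only.

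The comparisons, gene lists, alternatives and the rule for named genes were fixed before the data were examined, except for alternatives named as chosen later. The rule named Setdb1, Suv39h1, Tbx21, Ifng, Il12rb2, Stat4, Gata3, Il4, Il5 and Il13 always. Per comparison it took the 10 genes with the largest change each way at an adjusted p under 0.05, a mean of at least 50 and no overlap between groups, without predicted genes, and 5 each way per interaction. From each list it took up to 4 members with the largest change. The text names a selection of these: examples from lists were picked after their values were seen, and some members whose calls were lost under an alternative were left out, so the examples are steadier than the lists as a whole. Genes listed as shared by all 3 conditions were chosen after their values were seen. A gene that the rule named is not reported here.

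The 22 lists held Th1, Th2, Th17, Treg, Tfh, naive and quiescent, T cell activation, interferon-stimulated, CD8 and cytotoxic, NK and innate lymphoid receptor, B cell, myeloid, erythroid and platelet, cell cycle, p53 target and death, H3K9 methylation and heterochromatin, germline, clustered protocadherin beta, immediate early and heat shock, mitochondrially encoded, cholesterol synthesis and glycolysis genes. Each was tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison.

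Peaks on 21 chromosomes were counted as shared when they overlapped by at least 1 bp, and each share was set beside the mean of 100 random placements of the second list. Gene positions came from a RefSeq annotation of the GRCm38 assembly (mm10) matched by symbol or synonym, for 93.2% of tested genes. Because it gave no strand, distance was taken from the whole gene and not, as planned, from its start. Genes near peaks were compared with other tested genes by Fisher's exact test, two-sided, adjusted over 10 tests, and with a Mantel-Haenszel odds ratio over 10 classes of gene length, whose p came from a permutation test of calls within classes. No annotation of repeats was at hand, so endogenous retroviruses were not measured. Python 3.11.15 with scipy 1.17.1 and R 4.3.3 were used.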

Results

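Gene expression, 3 histone marks and open chromatin were measured in mouse splenic CD4 T cells to ask how the enzyme SETDB1 bears on the fate of T helper cells. SETDB1 and SUV39H1 both methylate lysine 9 of histone H3 (H3K9me3), a mark of silenced chromatin. Naive cells, which have not met antigen, were compared with T helper 2 (Th2) cells after 6 days of culture with IL-4. To test commitment, Th2 cells were moved for 2 days to medium with IL-12, the cytokine that drives T helper 1 (Th1) cells, and are called Th2-Th1 cells here. RNA was sequenced in 18 libraries: 4 naive wild-type (WT), 3 naive Setdb1 knockout (KO), 3 Th2 WT, 3 Th2 Setdb1 KO, 2 Th2-Th1 WT and 3 Th2-Th1 Setdb1 KO. Immunoprecipitated chromatin, input DNA and transposase-accessible chromatin (ATAC-seq) came from the remaining 22 samples, which the authors condensed into 13 peak lists, and Suv39h1 KO cells were profiled for H3K9me3 alone. Total reads per RNA library ran from 10.019 to 18.511 M in naive cells, from 10.141 to 13.258 M in Th2 WT and from 36.261 to 44.719 M in Th2 Setdb1 KO. They were 18.901 and 19.841 M in Th2-Th1 WT and 37.208 to 37.603 M in Th2-Th1 Setdb1 KO. RNA values below are the authors' normalised read counts, given as mean ± SD, and log2 differences carry a standard error from limma. The labels do not say that replicates were separate animals or cultures, so each p measures the spread between libraries only.

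The level of Setdb1, whose loss defines the KO groups, was examined first. In naive cells it was 1310 ± 66.4 (n = 4) in WT and 1006 ± 87.2 (n = 3) in libraries labelled Setdb1 KO, a log2 difference of -0.38 ± 0.11 (limma, adjusted p = 0.0319). That call was lost without naive WT replicate 1, 2 or 3 (adjusted p = 0.0695, 0.0675 and 0.0589) and without naive KO replicate 2 or 3 (adjusted p = 0.155 and 0.0608). It was also lost in a fit of the naive libraries alone (limma, adjusted p = 0.0686) and without a filter on low values (0.0625). Without 3 naive libraries that stood apart in genes detected the log2 difference was -0.31 (limma, adjusted p = 0.341). In Th2 cells the value went against the label: it was 822.6 ± 121 in WT and 8485 ± 503 in libraries labelled Setdb1 KO (n = 3 each), a log2 difference of 3.37 ± 0.12 (limma, adjusted p = 7.22e-14). In Th2-Th1 cells it was 1603 ± 12.1 (n = 2) in WT and 6244 ± 1020 (n = 3) in libraries labelled Setdb1 KO, a log2 difference of 1.95 ± 0.13 (limma, adjusted p = 3.04e-09). Every Th2 and Th2-Th1 library labelled Setdb1 KO lay above every WT library of its condition. The values sum reads over the whole gene and cannot separate deleted exons from the rest, so they do not measure how much intact transcript remained, and the groups are named by their labels throughout. Suv39h1 also rose in Th2 cells labelled Setdb1 KO, from 930.9 ± 79.0 to 1962 ± 73.5 (log2 1.08 ± 0.14, limma, adjusted p = 3.26e-06). It was 613.2 ± 100 and 582.5 ± 74.2 in naive cells, a difference that did not pass (adjusted p = 0.839).

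**Figure D1:**
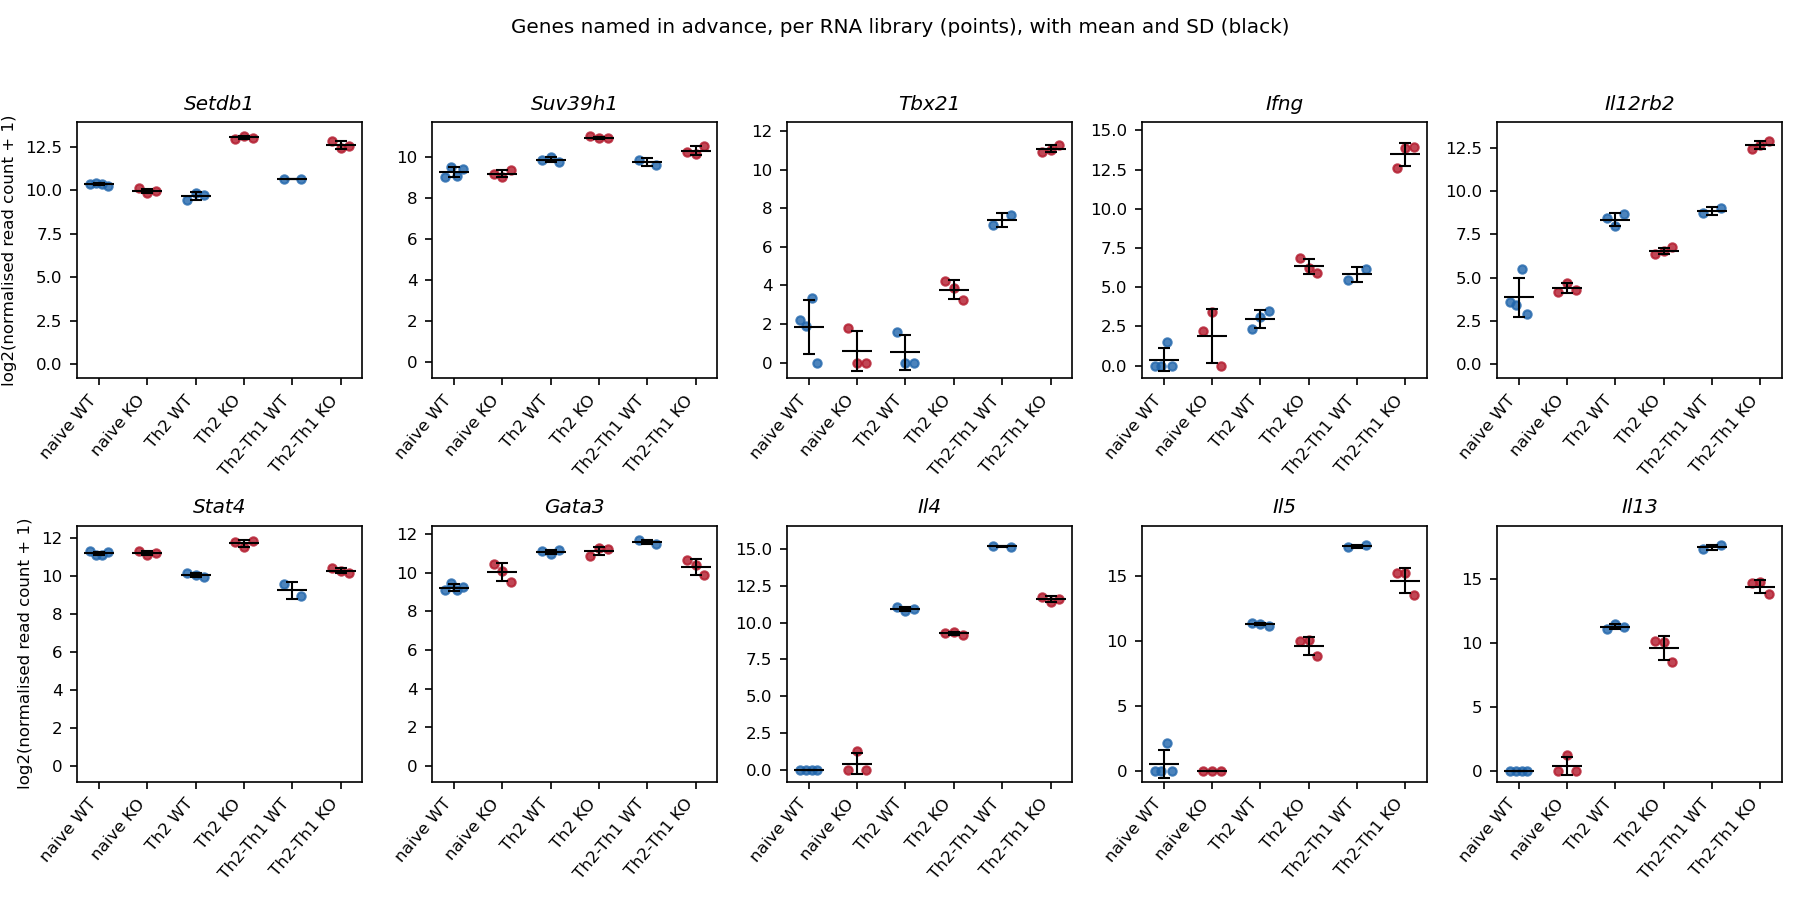
Log2 of the normalised read count plus 1 (vertical axis) of 10 genes chosen in advance in each RNA library, by group (horizontal axis); blue points are WT libraries, red points libraries labelled Setdb1 KO, and black bars the mean and SD. Setdb1 is higher in all 3 Th2 libraries labelled Setdb1 KO (mean 8485) than in all 3 Th2 WT libraries (mean 822.6), and Ifng reaches a mean of 12190 in Th2-Th1 libraries labelled Setdb1 KO against 57.29 in WT.

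Before culture, the comparison asked which genes depend on Setdb1 in naive cells. Cell division genes were the clearest group. Of 22 measured cell cycle genes 21 rose and none fell in libraries labelled Setdb1 KO, with a median log2 change of 2.55. Mki67, a marker of cycling cells, rose from 149.3 ± 89.2 (n = 4) to 3373 ± 511 (n = 3), and the mitotic kinase Aurkb from 3.405 ± 6.2 to 76.52 ± 17.4 (log2 5.07 ± 0.57). Birc5, which encodes survivin, rose by 4.08 ± 0.39 on the log2 scale, and Uhrf1, a reader of H3K9 methylation that also serves DNA methylation, by 3.12 ± 0.17. Tdrd9, a helicase of the germline piRNA pathway, had no reads in any WT library and a mean of 402.3 ± 140 in libraries labelled Setdb1 KO, at least 99.8-fold higher against a floor of 3 reads per library. The neuronal tubulin Tubb3 rose from 8.069 ± 4.4 to 701.2 ± 170 and the neuronal calcium channel gene Cacna1b from 8.957 ± 10 to 1075 ± 162. Among genes that fell were Epas1, which encodes HIF-2 alpha (287.1 ± 31.1 to 63.92 ± 29), F2rl1, a protease-activated receptor (1129 ± 171 to 270.6 ± 68.7), and the death ligand Fasl (397.2 ± 50.2 to 151.1 ± 44.6). Gata3, the master regulator of Th2 cells, rose from 603.4 ± 71.2 to 1082 ± 343 (log2 0.80 ± 0.19, limma, adjusted p = 0.0096), a call lost without naive KO replicate 1 (adjusted p = 0.0883), in a fit of the naive libraries alone (0.111) and without 3 naive libraries that stood apart in genes detected (0.282).

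Regulatory T cell (Treg) genes rose as a group in naive libraries labelled Setdb1 KO, with 5 of 13 higher and none lower over all genes tested and 8 higher when adjusted over the list alone. Il2ra, the alpha chain of the IL-2 receptor, rose by 2.59 ± 0.19 on the log2 scale and the transcription factor gene Ikzf4 by 2.08 ± 0.19. Of 23 genes of H3K9 methylation and heterochromatin 9 rose and 1 fell (10 and 1 adjusted over the list alone), among them Uhrf1 and the chromatin remodeller Hells (log2 1.38 ± 0.21). Interferon-stimulated genes were higher in 12 of 28 cases and lower in none (19 and 0 adjusted over the list alone), including Rsad2 (log2 1.95 ± 0.42) and Isg15 (1.52 ± 0.33). T cell activation genes were higher in 4 of 14 cases and lower in 1 (8 and 1 adjusted over the list alone), including Tnfrsf4 (log2 1.41 ± 0.13) and Tnfrsf9 (1.36 ± 0.22). In limma's camera test of a list against all other genes, the adjusted p was 1.07e-32 for the cell cycle, 1.04e-05 for Treg genes and 1.04e-05 for heterochromatin genes, and these calls held with an estimated correlation between genes. The interferon list (adjusted p = 2.39e-09) and the activation list (adjusted p = 0.000258) did not hold, with adjusted p = 0.464 and 0.058 with an estimated correlation. In a fit of the naive libraries alone the calls of Hells, Rsad2 and Isg15 were lost (adjusted p = 0.0731, 0.101 and 0.0872). No other list passed in this fit. Of 13 immediate early and heat shock genes, 11 B cell markers and 7 erythroid and platelet markers none was called, and 1 of 9 myeloid markers was higher. Of 5 NK and innate lymphoid receptor genes 1 was lower, of 14 p53 target and death genes 2 were higher and 1 lower, and of 9 germline genes 2 were higher. Of 21 clustered protocadherin beta genes 2 could be tested and neither was called, and the mitochondrially encoded genes had no reads in any library.

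Across all genes, 1877 of 17254 differed between naive libraries labelled Setdb1 KO and WT at an adjusted p under 0.05 (limma with Benjamini-Hochberg adjustment), 1282 higher and 595 lower, and 670 of them by at least 2-fold. Fitted on the naive libraries alone the count was 407, and without naive KO replicate 1 or 2 it was 1183 or 1076. Naive WT replicates 1 and 3 and naive KO replicate 2 stood apart, with 21283, 25556 and 22195 genes detected at equal depth against 15114 to 18607 in the others. Without these 3 libraries, an exclusion chosen after the data were seen, 890 genes were called. Of the cell cycle genes 20 then rose, but Rsad2 and Isg15 were not called (limma, adjusted p = 0.169 and 0.198), and by limma 0 of 28 interferon-stimulated genes passed (7 at an unadjusted p under 0.05, all higher). As a list these had a median log2 change of 0.73 and a camera adjusted p of 0.00053, which was 0.575 with an estimated correlation. Germline (median log2 1.12 against -0.15 with all libraries, adjusted p = 0.00516), cholesterol (0.00598) and Th17 genes (0.0457) also passed camera there, but not with an estimated correlation (adjusted p = 0.13, 0.22 and 0.267), and nor did heterochromatin genes (0.13). With a replicate block the cholesterol list passed as well (adjusted p = 0.0114).

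**Figure D2:**
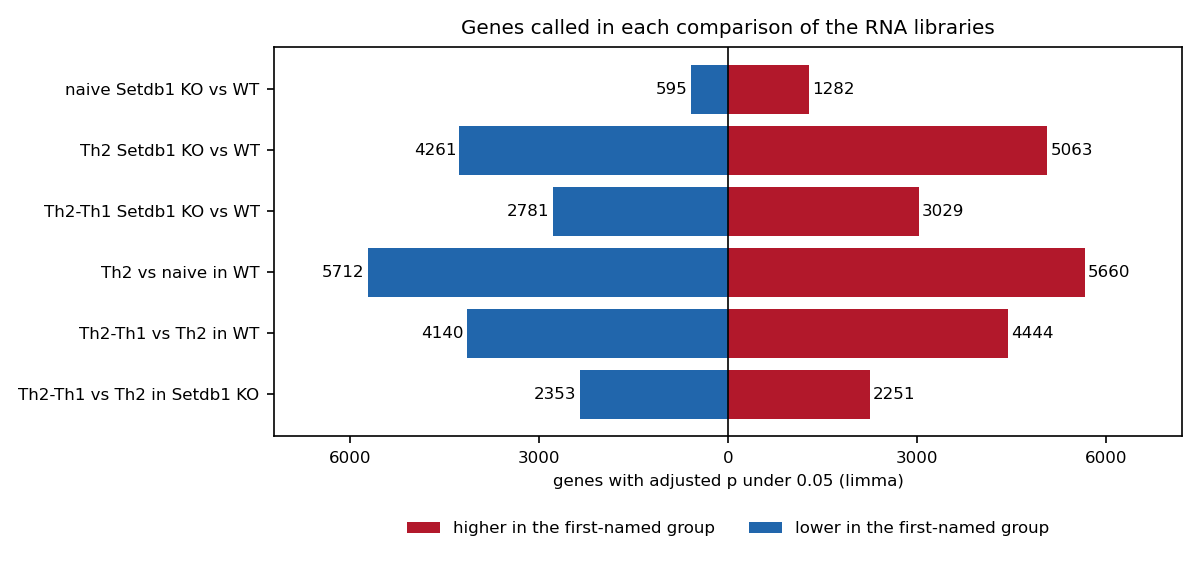
Number of genes with a limma adjusted p under 0.05 (horizontal axis) in each comparison of RNA libraries (vertical axis), higher in the first-named group to the right in red and lower to the left in blue. The fewest genes, 1282 higher and 595 lower, were called between naive libraries labelled Setdb1 KO and WT, and the most, 5660 higher and 5712 lower, between Th2 and naive WT.

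After 6 days of Th2 culture, glycolysis genes fell in libraries labelled Setdb1 KO, a call of the list that held with an estimated correlation between genes. Interferon-stimulated genes rose and genes of the Th2 programme fell, but as lists these did not hold (camera adjusted p = 0.325 each with an estimated correlation). Of 28 interferon-stimulated genes 24 were higher and 1 lower, with a median log2 change of 2.60. Rtp4 had no reads in WT and a mean of 132.1 ± 32.2 (n = 3), at least 20.8-fold higher. Ifit3, which encodes an antiviral RNA-binding protein, rose from 0.6721 ± 1.16 to 86.04 ± 34.9, and Oasl2 from 5.781 ± 5.04 to 140.5 ± 47.2. All 13 glycolysis genes fell, with a median of -1.60, among them Aldoa (149100 ± 10900 to 22890 ± 905, log2 -2.70 ± 0.10), Pgk1 (log2 -2.67 ± 0.14) and the glucose transporter gene Slc2a1 (log2 -2.25 ± 0.14). Of 21 Th2 genes 13 fell and 1 rose, with a median of -1.46. The Th2 cytokine genes fell together: Il4 from 1957 ± 209 to 616.9 ± 48.1 (log2 -1.66 ± 0.27), Il13 from 2560 ± 381 to 882.3 ± 448 (log2 -1.70 ± 0.37) and Il5 from 2491 ± 158 to 843.3 ± 340 (log2 -1.66 ± 0.50). The Il5 call was lost without Th2 KO replicate 3 (log2 -1.26, adjusted p = 0.0587). Maf, a transcription factor of Il4 (log2 -2.31 ± 0.25), Pparg (-2.71 ± 0.69) and the eotaxin receptor Ccr3 (-2.87 ± 0.76) fell as well. Gata3 did not pass, at 2169 ± 152 and 2240 ± 313 (adjusted p = 0.901).

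Of the opposing Th1 programme, Tbx21 and Ifng were at low levels in these cells. Tbx21, its master regulator T-bet, was 0.6721 ± 1.16 in Th2 WT and 13.27 ± 4.7 in libraries labelled Setdb1 KO (log2 3.25 ± 0.73, limma, adjusted p = 0.000917). Ifng, its signature cytokine, was 7.145 ± 2.98 and 82.6 ± 28.2 (log2 3.38 ± 0.69, adjusted p = 0.000349). Stat4, which transmits the IL-12 signal, rose from 1070 ± 75.2 to 3407 ± 413, whereas the IL-12 receptor gene Il12rb2 fell from 331.2 ± 78.2 to 92.75 ± 12.3. Ly6c2 and the related T-box gene Eomes also rose, to 1543 ± 324 and 107.8 ± 38.8. Of 26 Th1 genes 14 were higher and 4 lower, yet the list did not pass camera (adjusted p = 0.117). The genes that rose most included Fgl1, a fibrinogen-like ligand (2.581 ± 2.24 to 1932 ± 371), Map2, a neuronal microtubule protein (4.158 ± 7.2 to 997.6 ± 329), Nov, Sult5a1 and the pheromone receptor gene Vmn2r96. Sult5a1 had no reads in Th2 WT and was at least 92.6-fold higher. The neighbouring genes Ifi203 (1.504 ± 1.32 to 682.8 ± 188) and Pydc3 also rose, but reads of such close paralogs cannot be told apart with certainty. Among the genes that fell most were Fam183b (1676 ± 421 to 1.745 ± 1.56), Adm, which encodes adrenomedullin (1735 ± 260 to 3.948 ± 0.825), the receptor gene Slamf7 (7298 ± 881 to 22.8 ± 9.29), the circadian repressor Bhlhe41 (471.8 ± 19.8 to 2.567 ± 3.35) and the heat shock genes Hspa1a and Hspa1b.

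Cell cycle genes rose in 15 of 22 cases and fell in none in Th2 libraries labelled Setdb1 KO (17 and 0 adjusted over the list alone), among them Rrm2 (log2 2.35 ± 0.24) and Cenpf (2.26 ± 0.43). Of 23 heterochromatin genes 16 rose and 2 fell, including the silencing factor Morc2a (log2 2.38 ± 0.12). Follicular helper T cell (Tfh) genes fell in 7 of 10 cases and rose in 2, with Sh2d1a lower (log2 -2.80 ± 0.14). Naive and quiescent T cell genes went both ways: S1pr1, which lets T cells leave lymph nodes, fell (log2 -3.24 ± 0.12) while Foxp1 (2.91 ± 0.13) and Tcf7 (2.61 ± 0.21) rose, and 9 of 15 were lower. Of 13 immediate early and heat shock genes 8 fell and 1 rose, and of 8 Th17 genes 4 fell, including Ahr (log2 -2.65 ± 0.37) and Rora (-2.56 ± 0.24). Camera gave adjusted p = 3.58e-10 for glycolysis and 0.000132 for heterochromatin genes, and both held with an estimated correlation (adjusted p = 0.0283 and 0.0445). The calls of interferon-stimulated, Th2, cell cycle, immediate early, Tfh and quiescence genes did not, with adjusted p = 0.088 for Tfh genes and 0.325 for each of the others with an estimated correlation. In all, 9324 genes passed, 5063 higher and 4261 lower, 5801 of them by at least 2-fold. Depth and ribosomal protein reads differed between these groups as well: those reads made up 9.014 to 9.835% of reads in WT and 3.306 to 3.436% in libraries labelled Setdb1 KO. Rescaling with edgeR's TMM factors moved the median of all genes from 0.128 to 0.235, and the log2 changes given here are relative to the deposited scaling.

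**Figure D3:**
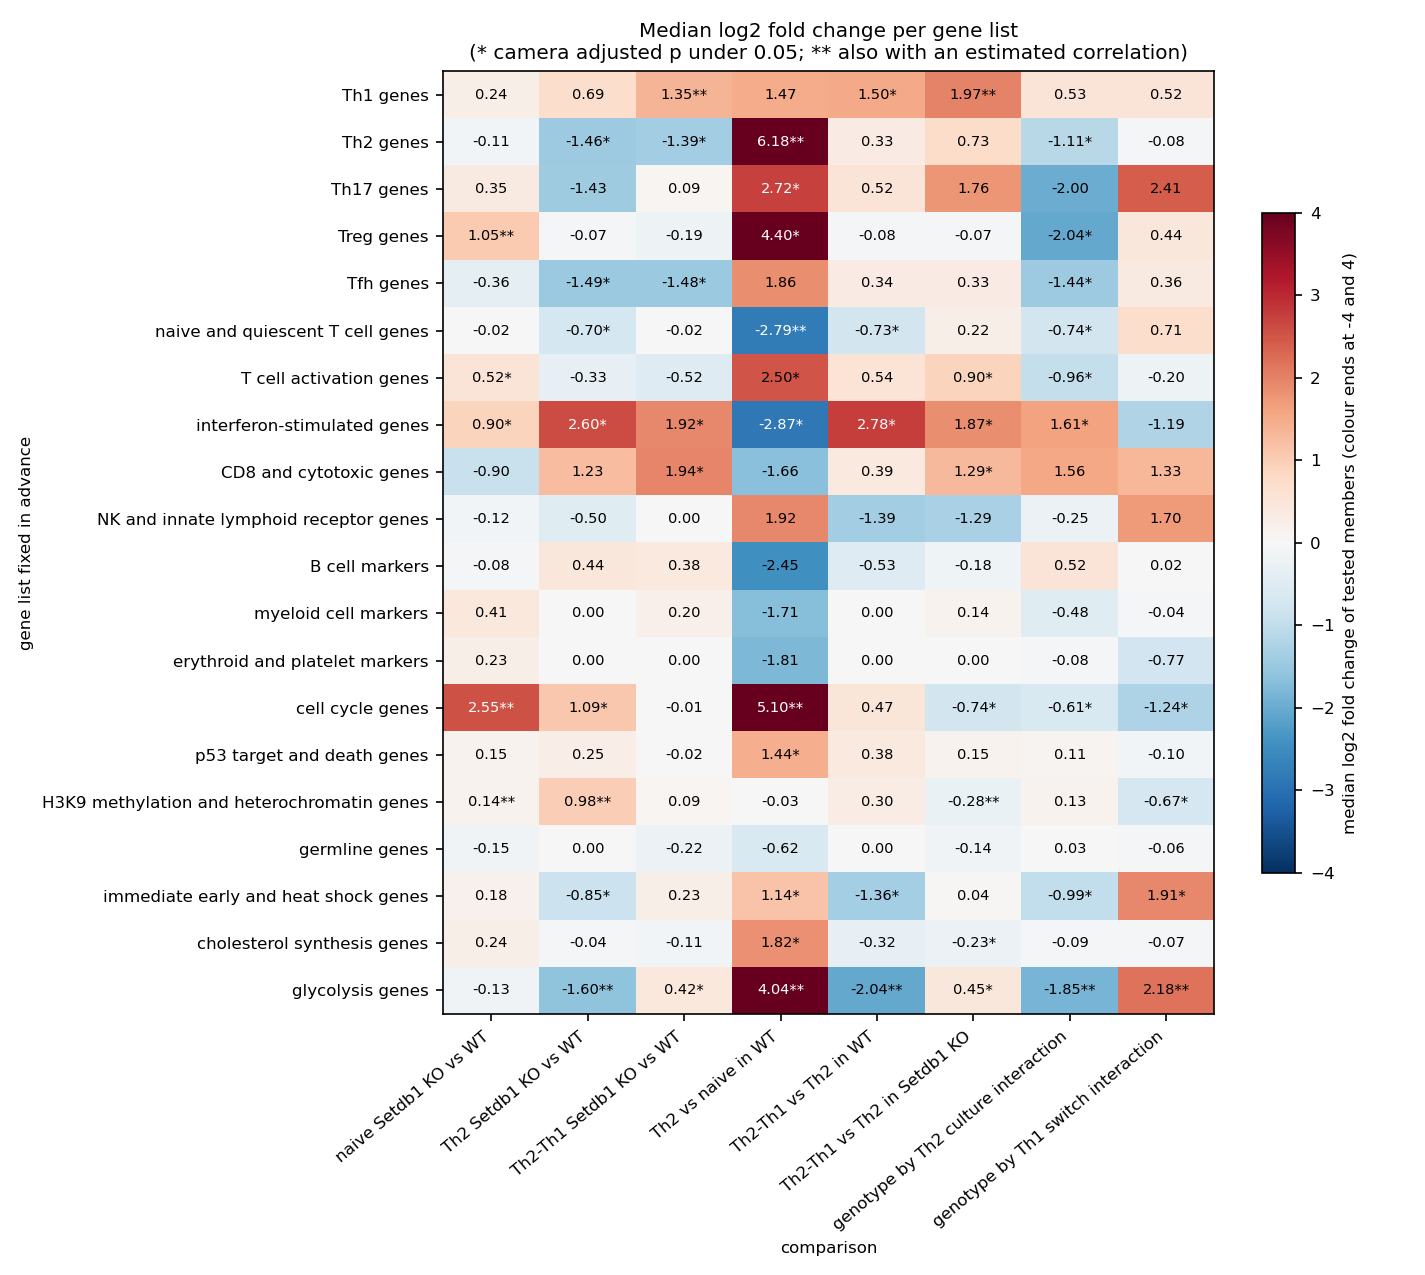
Median log2 fold change of the tested members (colour and number) of each of 20 gene lists (vertical axis) in the 6 comparisons and 2 interactions (horizontal axis); 1 star marks a camera adjusted p under 0.05 and a pair of stars a call that also held with an estimated correlation. Glycolysis genes had a median of -1.60 in Th2 libraries labelled Setdb1 KO and cell cycle genes a median of 2.55 in naive ones, and both calls held.

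When Th2 cells were exposed to Th1 conditions, the comparison asked whether cells labelled Setdb1 KO turned on Th1 genes that WT cells kept low. Ifng was 57.29 ± 19.2 (n = 2) in Th2-Th1 WT and 12190 ± 5150 (n = 3) in libraries labelled Setdb1 KO (log2 7.64 ± 0.77, limma, adjusted p = 4.08e-07). Tbx21 was 168.4 ± 42.8 and 2171 ± 281 (log2 3.70 ± 0.82) and Il12rb2 466.4 ± 73.2 and 6492 ± 966 (log2 3.79 ± 0.48). Of 26 Th1 genes 14 were higher and 2 lower (15 and 2 adjusted over the list alone), with a median log2 change of 1.35. Th2 cytokine genes were lower: Il4 was 37330 ± 1030 in WT and 3101 ± 424 in libraries labelled Setdb1 KO, Il13 186600 ± 25500 and 22910 ± 7080, and Il5 156100 ± 11300 and 28810 ± 14900. Gata3 fell from 3087 ± 253 to 1301 ± 353 (log2 -1.28 ± 0.23). Of 21 Th2 genes 11 fell and none rose, including the cytokine gene Il9 (log2 -4.78 ± 1.14).

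Other groups differed in Th2-Th1 cells too. Interferon-stimulated genes were higher in 23 of 28 cases and lower in none, for example Ifit3 (6.438 ± 0.753 to 190.7 ± 25.4) and Oasl2 (54.15 ± 45.4 to 541.7 ± 97.2). CD8 and cytotoxic genes were higher in 9 of 15 cases and lower in 1, among them the pore-forming protein gene Prf1 (38.02 ± 8.67 to 511.6 ± 314) and the NK receptor gene Klrc1 (12.92 ± 6.78 to 239.8 ± 96.9). Irf8, an interferon-regulated transcription factor, rose from 97.7 ± 19.6 to 1825 ± 84.3. Ly6c2, Serpina3f and Klrk1 were among the genes that rose most, from 0.5906 ± 0.835 to 1260 ± 530, from 1.772 ± 2.51 to 467.4 ± 54.7 and from 2.953 ± 4.18 to 307.9 ± 85.6. Akr1c18, an aldo-keto reductase, fell from 224500 ± 54200 to 3089 ± 714, the cystatin gene Stfa2 from 1052 ± 225 to 0.497 ± 0.501, Pth, which encodes parathyroid hormone, from 3203 ± 221 to 78.81 ± 45.8 and Gpr83 from 701.3 ± 37.2 to 15.69 ± 6.49. Of 10 Tfh genes 6 fell and 1 rose, with Slamf6 at -2.86 ± 0.28, and of 13 glycolysis genes 7 rose, with Eno1 at 1.94 ± 0.12. Camera passed for Th1 genes (adjusted p = 6.36e-05), which held with an estimated correlation (adjusted p = 0.0458). Calls of interferon-stimulated (4.94e-08), Th2 (0.00122), CD8 (0.013), Tfh (0.00898) and glycolysis genes (0.00898) gave adjusted p = 0.456, 0.35, 0.35, 0.0691 and 0.35 with an estimated correlation. Across all genes 5810 passed, 3029 higher and 2781 lower, 2676 by at least 2-fold. Without Th2-Th1 WT replicate 2 the count was 3847, and WT had only 2 libraries.

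Th2 culture of WT cells served as the reference for polarisation. Il4 and Il13 had no reads in 4 naive WT libraries and means of 1957 ± 209 and 2560 ± 381 (n = 3) in Th2 WT, at least 486-fold and 635-fold higher. Il5 rose from 0.9053 ± 1.81 to 2491 ± 158, Gata3 from 603.4 ± 71.2 to 2169 ± 152, and Il10 and Il24 to 8759 ± 1110 and 14280 ± 731. Of 21 Th2 genes 20 rose and none fell, with a median log2 change of 6.18. Cell cycle genes rose in 21 of 22 cases (22 adjusted over the list alone), among them Aurkb (log2 10.07 ± 0.57), and 12 of 13 glycolysis genes rose and 1 fell, among the former the hexokinase gene Hk2 (9.13 ± 0.49) and Tpi1 (6.87 ± 0.18). The cholesterol synthesis gene Fdps rose by 4.54 ± 0.18 on the log2 scale, as did 14 of 15 genes of that pathway. Naive and quiescent genes fell in 14 of 15 cases, among them Tcf7 (14030 ± 1300 to 109.9 ± 18.9) and Foxp1 (7786 ± 152 to 239.2 ± 14.7). Interferon-stimulated genes fell in 22 of 28 cases and rose in 1 (24 and 1 adjusted over the list alone), for example Ifit3 (899.3 ± 398 to 0.6721 ± 1.16). Markers of other cell types fell as well: B cell markers in 6 of 11 cases (median log2 -2.45), erythroid and platelet markers in 4 of 7 (-1.81) and myeloid markers in 4 of 9 with 1 higher (-1.71). As lists these did not pass camera (adjusted p = 0.104, 0.0991 and 0.503), though B cell markers did with a replicate block (0.0411). Activation genes rose in 10 of 14 cases and fell in 3, and Treg genes in 9 of 13 with 3 lower, with Il2ra, which is in both lists, at 9.81 ± 0.19 and the inhibitory receptor gene Ctla4, a Treg gene here, at 7.19 ± 0.19. The serine protease gene Gzmb, the receptor gene Tnfrsf8 (CD30) and the transglutaminase Tgm2 were among the largest gains, to 14960 ± 697, 26470 ± 878 and 49070 ± 1220, and Dapl1 and Txk were among the largest losses. With camera, Th2 (adjusted p = 4.09e-10), cell cycle (5.61e-12), glycolysis (1.37e-09) and quiescence genes (1.09e-06) passed and held with an estimated correlation (adjusted p = 0.0327 for each). Interferon-stimulated (1.09e-07), cholesterol (7.65e-06), activation (0.00117) and Treg genes (0.00332) gave adjusted p = 0.317, 0.15, 0.0768 and 0.0768 with an estimated correlation. Th17 (6 of 8 higher), p53 target (11 of 14 higher, 3 lower) and immediate early genes (7 of 13 higher, 2 lower) also passed, at 0.0459, 0.017 and 0.0459, with adjusted p = 0.317, 0.242 and 0.413 with an estimated correlation. In total 11372 genes passed, 5660 higher and 5712 lower, 8011 by at least 2-fold.

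In WT Th2 cells moved to Th1 conditions, Th2 cytokine genes rose further, and of the Th1 genes Tbx21 and Ifng rose from low levels. In neither genotype was a group kept in Th2 medium for those 2 days. Changes after the move therefore cannot be told apart from those of further culture, also in the interaction below. Il4 rose from 1957 ± 209 (n = 3) to 37330 ± 1030 (n = 2; log2 4.26 ± 0.30), Il5 by 5.97 ± 0.56 and Il13 by 6.19 ± 0.42 on the log2 scale. Tbx21 rose from 0.6721 ± 1.16 to 168.4 ± 42.8 and Ifng from 7.145 ± 2.98 to 57.29 ± 19.2 (log2 2.87 ± 0.77, limma, adjusted p = 0.00409). Without Th2-Th1 WT replicate 2 the Ifng call was lost (adjusted p = 0.0512). Il12rb2 was 331.2 ± 78.2 and 466.4 ± 73.2, which did not pass (adjusted p = 0.407), and Stat4 fell from 1070 ± 75.2 to 625.4 ± 186. Of 26 Th1 genes 15 rose and 5 fell (15 and 6 adjusted over the list alone). The inhibitory receptor Havcr2 rose to 9371 ± 796, the chemokines Ccl3 and Ccl4 to 5380 ± 2440 and 2581 ± 357, and Il3 to 11250 ± 709. Of 28 interferon-stimulated genes 25 rose and none fell, among them Ifi44 (1.291 ± 1.12 to 148.8 ± 109), and 12 of 13 glycolysis genes fell, among them Pdk1 (log2 -3.06 ± 0.14) and Eno1 (-2.98 ± 0.12). Fos (log2 -3.22 ± 0.41) and Hspa1a (-4.30 ± 0.43) were among 8 of 13 immediate early and heat shock genes that fell, and Igfbp4 (-5.88 ± 0.18) and Ccr7 (-3.42 ± 0.13) among 9 of 15 quiescence genes. Camera gave adjusted p = 3.15e-10 for glycolysis, which held with an estimated correlation (adjusted p = 0.031). Interferon-stimulated (2.95e-10), Th1 (0.0146), quiescence (0.0113) and immediate early genes (0.00907) gave adjusted p = 0.481, 0.289, 0.369 and 0.484 with an estimated correlation. In this comparison 8584 genes passed, 4444 higher and 4140 lower. Total reads did not overlap between these groups, at 10.141 to 13.258 M in Th2 WT and 18.901 and 19.841 M in Th2-Th1 WT. Ribosomal protein reads were 9.014 to 9.835% in the former and 4.201 and 4.327% in the latter. No batch was given, so a library batch cannot be told apart from the move.

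The same move in cells labelled Setdb1 KO brought large gains of Th1 genes. Ifng rose from 82.6 ± 28.2 to 12190 ± 5150 (n = 3 each; log2 7.13 ± 0.69), Tbx21 from 13.27 ± 4.7 to 2171 ± 281 (7.30 ± 0.73) and Il12rb2 from 92.75 ± 12.3 to 6492 ± 966 (6.11 ± 0.43). Il4 and Il13 also rose, from 616.9 ± 48.1 to 3101 ± 424 and from 882.3 ± 448 to 22910 ± 7080, while Gata3 fell from 2240 ± 313 to 1301 ± 353. Of 26 Th1 genes 18 rose and 2 fell (19 and 2 adjusted over the list alone), with a median log2 change of 1.97. Interferon-stimulated genes rose in 23 of 28 cases (24 and 1 lower adjusted over the list alone), including Ifi44 (log2 5.33 ± 0.52). Klrk1 (6.83 ± 1.13) and Klrc1 (6.55 ± 0.83) were among 8 of 15 CD8 and cytotoxic genes that rose, and 3 fell. Cell cycle genes fell in 10 of 22 cases and rose in 1 (15 and 1 adjusted over the list alone), including Ccnb2 (log2 -1.48 ± 0.38), and 9 of 23 heterochromatin genes fell, including the H3K9 methyltransferase Ehmt2 (-0.85 ± 0.10). The cytokine genes Il21 and Il3 were among the largest gains (to 4037 ± 1240 and 2284 ± 372), and Il17rb (467.4 ± 64.2 to 6.094 ± 4.57), Cpa3 and Slamf6 among the largest losses. Setdb1 itself fell from 8485 ± 503 to 6244 ± 1020, a call lost without Th2-Th1 KO replicate 2 (adjusted p = 0.0574). Camera gave adjusted p = 6.71e-10 for Th1 genes and 0.000206 for heterochromatin genes, and both held with an estimated correlation (adjusted p = 0.00241 and 0.047). Interferon-stimulated (8.73e-14), activation (0.000425), CD8 (0.0105) and cell cycle genes (0.000307) gave adjusted p = 0.231, 0.0913, 0.231 and 0.271 with an estimated correlation. Activation genes were higher in 9 of 14 cases and lower in 1 (10 and 2 adjusted over the list alone). Glycolysis (8 of 13 higher, 1 lower; 0.00891) and cholesterol genes (5 of 15 lower; 0.0329) gave adjusted p = 0.271 and 0.595 with an estimated correlation. Together 4604 genes passed, 2251 higher and 2353 lower.

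Whether the response to Th1 conditions differed between genotypes was tested as an interaction, in which 6126 genes passed, 2979 with a more positive log2 response in libraries labelled Setdb1 KO and 3147 with a more negative one. These are signed differences and do not say which genotype changed more. Il12rb2 (log2 difference 5.60 ± 0.64, adjusted p = 1.51e-06) and Ifng (4.26 ± 1.03, adjusted p = 0.00301) rose more in libraries labelled Setdb1 KO (limma). Rab34 (7.86 ± 1.14) and the metallothionein gene Mt2 (7.91 ± 0.51) fell in WT, from 139.1 to 16.51 and from 3192 to 623.1, and rose in libraries labelled Setdb1 KO, from 1.858 to 51.72 and from 112.7 to 5249. Tbx21 did not differ detectably in its response (0.45 ± 1.10, limma, adjusted p = 0.809), but passed when 5 rather than 1 was added before the logarithm (1.99, adjusted p = 0.00803). Gata3 (-1.32 ± 0.30), Il4 (-1.94 ± 0.40) and Il9 (-6.56 ± 1.52) had a more negative response. Glycolysis genes had a more positive response in 12 of 13 cases, with Eno1 at 3.44 ± 0.16 and Pgk1 at 3.15 ± 0.21 (camera adjusted p = 1.14e-14, and 0.00654 with an estimated correlation). The median log2 change of that list after the move was -2.04 in WT and 0.45 in libraries labelled Setdb1 KO, so the difference came mainly from the fall in WT. The same Th2 WT libraries enter that fall, the Th2 comparison (median -1.60) and both interactions. These glycolysis calls are therefore not independent of each other. Cell cycle genes had a more negative response in 12 of 22 cases (13 adjusted over the list alone), among them Cenpf (-2.52 ± 0.64), with camera adjusted p = 8.97e-05 and adjusted p = 0.449 with an estimated correlation. Heterochromatin genes (13 of 23 more negative, 4 more positive; adjusted p = 0.00468) and immediate early and heat shock genes (6 of 13 more positive; adjusted p = 0.00781) gave adjusted p = 0.156 and 0.578 with an estimated correlation.

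The effect of the Setdb1 KO label also differed between naive and Th2 cells, with 7122 genes past the threshold of that interaction, 3575 with a more positive effect in Th2 cells and 3547 with a more negative one. This balance moved with the processing, to 4265 and 3059 with TMM scaling, 3902 and 2988 with edgeR, and 3121 and 3573 without the 3 naive libraries that stand apart. Setdb1 itself (3.76 ± 0.16), Tbx21 (4.52 ± 1.00) and Stat4 (1.65 ± 0.18) were among the former, and Il12rb2 (-2.34 ± 0.58) among the latter, all by limma. Il4 (-2.08 ± 0.37) and Il13 (-2.12 ± 0.51) had 0 reads in naive WT and 1 in naive libraries labelled Setdb1 KO, so their values restate the difference in Th2 cells. Their calls were lost with edgeR (adjusted p = 0.148 and 0.502) and DESeq2 (adjusted p = 0.184 and 0.247). The effect was more negative for 12 of 13 glycolysis genes, with Slc2a1 at -2.54 ± 0.20 (camera adjusted p = 1.75e-10, and 0.0252 with an estimated correlation). It was more positive for 16 of 28 interferon-stimulated genes and more negative for 2, with Ifit3 at 4.92 ± 0.72 (camera adjusted p = 0.000476, and adjusted p = 0.503 with an estimated correlation). The Th2 (0.0057), Treg (0.0125), activation (0.0126), immediate early (0.00471), Tfh (0.0404), quiescence (0.0404) and cell cycle lists (0.0404) went to the negative side, with adjusted p = 0.329, 0.224, 0.261, 0.329, 0.224, 0.329 and 0.503 with an estimated correlation. TMM scaling moved the median of all genes in this interaction from 0.103 to 0.240.

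More genes were called in the same direction in several conditions than if calls were independent. Of the genes higher in naive cells 687 were also higher in Th2 cells, where 376.2 would be shared if calls were independent, and 1629 genes were higher in both Th2 and Th2-Th1 cells against 888.8. In all 3 conditions 327 genes were higher (66.0 if independent) and 214 lower (23.7). Of genes higher in naive cells 224 were lower in Th2 cells, and of those higher in Th2 cells 438 were lower in Th2-Th1 cells. The independent counts treat every gene as equally easy to call. Depth followed the label in Th2 and Th2-Th1 cells, so shared calls there cannot be told apart from a library batch. The number of naive calls also depended on the processing. Tdrd9, Tubb3, the meiotic cohesin gene Stag3, the pheromone receptor gene Vmn2r96, the T cell receptor gene Tcrg-C2 and Zfp683, which encodes the lymphocyte factor Hobit, were among those higher in all 3. Zfp683 stayed low, with means of 13.19, 22.74 and 13.04 in naive, Th2 and Th2-Th1 libraries labelled Setdb1 KO. Tdrd9 had a mean of only 10.63 in the Th2 ones. Tenm1 and Prss12 were among those lower in all 3. The naive call of Prss12 was lost without the 3 naive libraries that stand apart (limma, adjusted p = 0.0952).

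H3K9me3 peak lists were far shorter in Setdb1 KO cells. Naive WT cells had 9659 peaks covering 13.66 Mb and naive Setdb1 KO cells 1163 peaks covering 2.29 Mb. Th2 WT cells had 12233 peaks covering 19.5 Mb, Th2 Setdb1 KO cells 1708 covering 2.56 Mb and Th2 Suv39h1 KO cells 43404 covering 77.04 Mb. Of the naive WT peaks 746 (7.72%, Wilson 95% interval 7.21 to 8.27) were overlapped by a Setdb1 KO peak, against 0.17% when KO peaks were placed at random. Of the Th2 WT peaks 539 (4.41%) were overlapped by a Setdb1 KO peak (0.21% at random) and 11726 (95.86%) by a Suv39h1 KO peak (5.91% at random). Of the naive Setdb1 KO peaks 65.0% overlapped a WT peak, but of the Th2 Setdb1 KO peaks only 30.97% did, and 1179 had no WT counterpart. The Suv39h1 KO list held 32057 peaks with no WT counterpart. Of naive WT peaks 54.39% were overlapped by a Th2 WT peak (1.57% at random). Each condition had a single list with no replicates to test against. The naive Setdb1 KO list came from 1 sample and each other H3K9me3 list from 2. Read depth behind the lists is not given in the sources used here. Differing depth or sample number could therefore not be excluded as a source of differing length.

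Of 16086 tested genes with a position, 8979 lay within 50 kb of a Th2 WT H3K9me3 peak absent in Setdb1 KO and 796 near any Th2 Setdb1 KO peak, so the lack of a KO peak at a given gene followed largely from the short list. Peaks at Th1 genes are given with that limit. Within 50 kb of Ifng (chromosome 10, 118441046 to 118445894, mm10) there were 5 H3K9me3 peaks in Th2 WT, 1 in naive WT, none in Setdb1 KO and 5 in Suv39h1 KO. All 5 Th2 WT peaks lay outside the gene, the longest at 118462051 to 118465300. Tbx21 (chromosome 11, 97098007 to 97115331) had 1 such peak in Th2 WT, at 97087851 to 97090300, and 3 in naive WT, against none in Setdb1 KO and 5 in Suv39h1 KO. Stat4 (chromosome 1, 51987106 to 52107189) had 5 in Th2 WT, and Il12rb2 (chromosome 6, 67285986 to 67376293) had none in Th2 WT and 2 in naive WT. Th2 genes carried such peaks as well. Il4 (chromosome 11, 53612460 to 53618665) had 6 in Th2 WT, none in naive WT, none in Setdb1 KO and 9 in Suv39h1 KO, and Gata3 (chromosome 2, 9857078 to 9887953) had 1 in each WT list and none in Setdb1 KO.

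**Figure D4:**
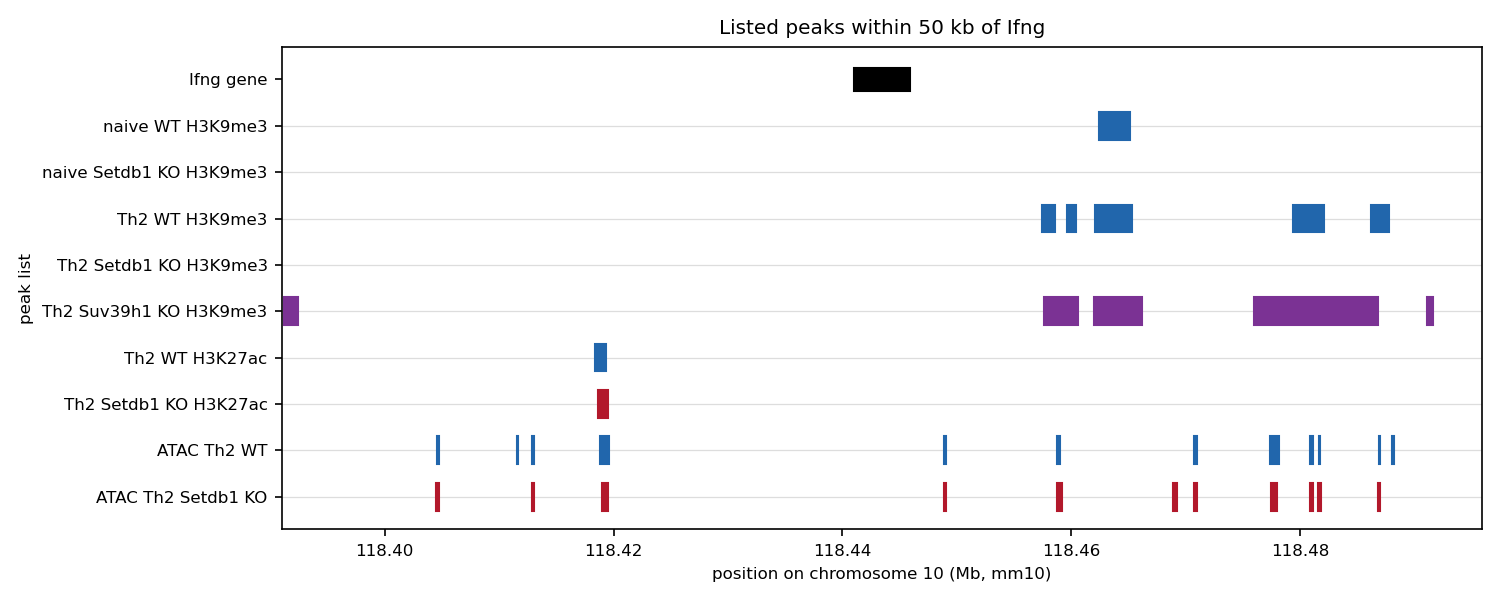
Listed peaks (boxes) of 9 ChIP-seq and ATAC-seq lists (vertical axis) within 50 kb of Ifng, by position on chromosome 10 (Mb, mm10, horizontal axis); black marks the gene, blue WT, red Setdb1 KO and purple Suv39h1 KO. The 5 H3K9me3 peaks of Th2 WT lie to the right of the gene, and the Setdb1 KO lists hold none in the window.

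Marks of active chromatin overlapped more between genotypes. H3K27ac, a mark of active enhancers and promoters, had 31236 peaks (52.83 Mb) in Th2 WT and 40734 (47.17 Mb) in Th2 Setdb1 KO; 77.91% of WT peaks were overlapped by a KO peak (4.68% at random), and 11824 KO peaks had no WT counterpart. H3K4me1, a mark of enhancers, had 76271 peaks (124.3 Mb) in WT and 97052 (120.97 Mb) in Setdb1 KO, with 79.0% of WT peaks overlapped (10.61% at random) and 29959 found in KO alone. Accessible regions numbered 92129 (33.53 Mb) in WT and 58523 (20.68 Mb) in Setdb1 KO, and 56.64% of WT regions were overlapped (1.67% at random). Each of these WT and Setdb1 KO lists came from 1 sample. H3K27ac peaks were shorter in the KO list, with a median length of 613 bp against 1141 bp in WT. Between H3K4me1 lists from separate experiments on Th2 WT cells, 90.32% of peaks of the first were overlapped (10.44% at random). Of the second, the WT list set against Setdb1 KO above, 80.51% were overlapped (8.75% at random). Of naive WT H3K4me1 peaks 78.49% were overlapped in Th2 WT (9.75% at random). Near Setdb1 (chromosome 3, 95323525 to 95357202) the H3K27ac list held 8 peaks in WT and 14 in Setdb1 KO, within 50 kb of the gene.

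Gene calls were then set beside the peak lists, with a peak counted as near when it lay within 50 kb of the gene. Of 4826 genes higher in Th2 libraries labelled Setdb1 KO, 3098 (64.2%) had a nearby H3K27ac peak found in KO alone, against 56.6% of other genes (odds ratio 1.374, Fisher's exact test, two-sided, p = 2.8e-19). For H3K4me1 the shares were 93.0% and 86.0% (odds ratio 2.17, exact p = 1.65e-39) and for accessible regions 38.6% and 35.0% (1.169, p = 1.23e-05). The same genes also lay more often near accessible regions found in WT alone, 93.4% against 90.4% (odds ratio 1.515, exact p = 1.34e-10). Genes lower in these libraries showed no such excess for H3K27ac (odds ratio 0.995, exact p = 0.897) or H3K4me1 (0.916, p = 0.116), and for accessible regions had an odds ratio of 0.926 (p = 0.0449, adjusted p = 0.0641 over the 10 tests). H3K9me3 peaks of Th2 WT that were absent in Setdb1 KO lay near 57.6% of genes higher in these libraries and 55.0% of other genes (odds ratio 1.111, Fisher's exact test, p = 0.00258), and genes lower in them had 1.121 (p = 0.00186). When genes were grouped by length, an alternative chosen after the data were seen, higher genes had 1.016 (permutation p = 0.656). Lower genes then had 1.261 (permutation p = 1e-05, the smallest the permutations can give). In naive cells 60.0% of genes higher in libraries labelled Setdb1 KO and 53.2% of others lay near an H3K9me3 peak absent in KO (odds ratio 1.324, Fisher's exact test, p = 2.63e-06), and genes lower in them had 1.124 (p = 0.175). Grouped by length the values were 1.185 (permutation p = 0.00577) and 1.293 (permutation p = 0.00356), so the higher genes did not then stand out from the lower ones. Without that grouping the higher genes had the larger value at 20 kb (1.301 against 0.997) and 100 kb (1.302 against 1.105). The difference between higher and lower genes was not tested. Genes are not independent replicates, and distances ran from the whole gene because strand was not given. Each list of H3K27ac, H3K4me1 or accessible regions used here came from 1 sample. The p values therefore carry no spread between samples, and peaks found in 1 genotype alone could reflect how a single sample was called.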

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

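All tests of explanations in this part were chosen after the result was seen; the interactions were planned. Of 74 results tested in the 4 naive WT libraries 12 had 1 library far from the other 3. Chance marks about 1 in 20, but that rate does not hold for the 8 of them with 0 in the other 3 libraries. Replicate 3 stood apart for Aurkb (12.67 against 0 to 0.9447), Il12rb2 (43.45 against 6.613 to 11.23), Emilin2 (19.92), Cyp11a1 (9.053), Nts (5.432) and Il5 (3.621), and for Ifng, Mt1 and Tnfrsf8 at 1.811 each, with 0 in the others unless given. In replicate 3 the value 1.811 stands for 1 read. Replicate 1 stood apart for Gzmb (8.732 against 0), and replicate 4 for Foxp1 (8011 against 7680 to 7732) and Ms4a4b (7315 against 5527 to 5595). Il12rb2 in naive libraries labelled Setdb1 KO passed without naive WT replicate 3 (log2 1.08, limma, adjusted p = 0.0073).

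The response to Th1 conditions differed between genotypes for 6126 genes by the limma interaction. It was more positive in libraries labelled Setdb1 KO for Tbkbp1 (log2 8.57), Smtnl2 (8.13), Irf8 (8.0), Mt2 (7.91), Rab34 (7.86), Il12rb2 (5.60), Ifng (4.26), Eno1 (3.44) and Pgk1 (3.15). It was more negative for Sult5a1 (-7.11), Cacna2d1 (-7.04), Il9 (-6.56), Anxa1 (-6.34), Cpa3 (-6.23), Cenpf (-2.52), Il4 (-1.94), Setdb1 (-1.43), Gata3 (-1.32) and Stat4 (-0.63). These signed differences do not say which genotype changed more. The call of Stat4 was lost without Th2-Th1 WT replicate 1 (limma, adjusted p = 0.228) or Th2 KO replicate 3 (0.0528), with reads thinned to the smallest library (0.0516) and in a fit of the groups compared alone (0.0565), and edgeR did not call Cpa3 (adjusted p = 0.13) or Sult5a1.

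The effect of the Setdb1 KO label differed between naive and Th2 cells for 7122 genes. It was more positive in Th2 cells for Sult5a1 (9.66), Fgl1 (9.11), Nov (8.77), Cacna2d1 (8.77), Map2 (8.53), Ifit3 (4.92), Tbx21 (4.52), Setdb1 (3.76), Stat4 (1.65) and Suv39h1 (1.15). It was more negative for Tgm2 (-10.11), Adm (-9.90), Apln (-8.53), Dpf1 (-8.52), Cyp2s1 (-8.39), Slc2a1 (-2.54), Il12rb2 (-2.34), Il13 (-2.12), Il4 (-2.08) and Gata3 (-0.76). The call of Gata3 was lost without naive WT replicate 1 or 3 (limma, adjusted p = 0.0624 and 0.0543), naive KO replicate 1 or 2 (0.119 and 0.0707), Th2 WT replicate 1 or 3 (0.0626 and 0.0743) or Th2 KO replicate 1 (0.1). It was also lost with TMM scaling (0.0866), with edgeR (0.0595), without a filter on low values (0.0735) and without the 3 naive libraries that stand apart (0.237). Il4, Il13 and Nov had at most 1 read in either naive group, so their values restate the difference in Th2 cells, and neither edgeR (adjusted p = 0.148 and 0.502) nor DESeq2 (0.184 and 0.247) called Il4 or Il13. Of 100 splits drawn with the real one, 6 gave as many genes, so chance could not be excluded by this count; the real split gave 7122 and the highest other 7969. The 5 others as large all kept the real split of the Th2 libraries, and among splits that did not keep it the highest was 302.

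Other splits of the naive libraries gave at most 1244 genes against 1877, and of 35 splits only 1, the real one, reached that. This is the smallest share that 35 splits can give, so chance was made unlikely but not excluded. The split with 1244 genes grouped naive WT replicates 1 and 3 with naive KO replicate 2, the libraries that stand apart. For Th2 against naive WT, 1 of 35 splits reached 11372 and the highest other gave 8552, so chance was unlikely there too. A split that calls 8552 genes shows the strong structure of these samples. The 10 splits of the Th2 libraries (9324 genes, highest other 0) and of the KO libraries moved to Th1 conditions (4604, highest other 0) are too few for a share under 0.05.

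Setdb1 was higher, not lower, in Th2 and Th2-Th1 libraries labelled Setdb1 KO. Exchanged labels of the Th2 RNA libraries would place genes called higher near active marks of WT alone, but grouped by length they lay more near those of KO alone (ratio of odds ratios 1.545 for H3K27ac, 95% bootstrap interval 1.411 to 1.688, and 1.934 for H3K4me1) and lower genes less (0.774 and 0.757), which argues against an exchange in Th2 cells. ATAC did not decide (0.876, 0.755 to 1.015). The bootstrap resampled genes and each of these lists came from 1 sample, so the intervals carry no spread between samples. Of genes higher in naive cells 687 were higher and 224 lower in Th2 cells. In Th2-Th1 cells 480 were higher and 121 lower, which argues against an exchange there. Greater depth as the whole cause is argued against by reads thinned to equal depth (log2 3.34 ± 0.12). The ratio of H3K27ac length in KO over WT at Setdb1 was at percentile 99.3 of tested genes, so a more active locus that still transcribes a disrupted gene may account for the value; reads per exon were not analysed here.

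Many genes were called between Th2 libraries labelled Setdb1 KO and WT, which also differed in depth and in ribosomal protein reads. With reads thinned to equal depth 95.8% of called genes still tested kept their call and direction, which argues against depth as the whole cause. With ribosomal protein, histone and predicted genes left out before scaling 94.0% did. That checks only the weight of these genes in the scaling. It cannot decide on a wider difference between libraries that goes along with the ribosomal protein share. A library batch that follows the genotype label may contribute and cannot be told apart from genotype, since the smallest KO library had 2.74 times the reads of the largest WT library and no batch was given. Depth also separated the genotypes in Th2-Th1 cells, at 37.208 to 37.603 M reads in KO and 18.901 to 19.841 M in WT. The same limit holds there and in both interactions. Depth did not overlap between Th2 WT and Th2-Th1 WT either, so batch cannot be told apart from the move in WT cells.

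Cell cycle genes rose in naive libraries labelled Setdb1 KO. Without the 3 naive libraries that stand apart their median log2 change was 2.84 with 20 higher, which argues against those libraries as the cause. Activated T cells among the naive cells may contribute: activation genes had a median of 0.52, but their call was lost with an estimated correlation (camera adjusted p = 0.058), and naive and quiescent genes had a median of -0.02. This stays open, and proliferation without activation was not tested.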

How the results depend on the processing

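The alternatives with reads thinned to the smallest library, without the 3 naive libraries that stand apart, without ribosomal protein, histone and predicted genes before scaling, and grouped by gene length were chosen after the data were seen. Counts of genes stayed within 1.5 times in 151 of 156 settings. The count for naive libraries labelled Setdb1 KO was 1877, but 407 when only the groups compared were fitted and 890 without the 3 naive libraries that stand apart, and it ran from 1076 to 2499 with 1 library left out. That for Th2-Th1 libraries was 5810 and ran from 3847 to 5181. The other ranges with 1 library left out were 8346 to 8786 in Th2, 10767 to 11601 for Th2 against naive WT, 6963 to 8151 and 3523 to 4169 for the move to Th1 conditions in WT and KO, and 4974 to 5905 and 6360 to 7174 for the interactions. Replicate numbers did not clearly pair the libraries (correlations of -0.411 to 0.011 between naive groups and 0.009 to 0.13 between Th2 KO and Th2-Th1 KO). With a replicate block the counts were 1775 in naive, 9359 in Th2 and 5832 in Th2-Th1 cells. edgeR called 1924, 9386 and 6176 genes in these comparisons and DESeq2 2560, 9371 and 6392. Of 5402 values of named genes under alternatives none turned its direction past the threshold, 63 lost and 20 gained a call. These genes include the largest changes and list examples from which some unstable members were left out. The counts therefore do not measure how steady other genes were. Of 160 list tests 56 passed, and 15 with an estimated correlation. The cause of these changes was not tested.

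Shares of overlapped peaks moved. With at least 50% of the peak overlapped they were 4.34% (naive H3K9me3, Setdb1 KO), 2.65% (Th2 H3K9me3, Setdb1 KO), 94.75% (Suv39h1 KO), 48.76% (H3K9me3, naive by Th2), 64.16% (H3K4me1, naive by Th2), 61.75% (H3K4me1, KO), 61.2% (H3K27ac), 45.5% (ATAC) and 78.87% (H3K4me1, both experiments). With the peaks above the median score of each list they were 94.52% (Suv39h1 KO), 46.85% (H3K9me3, naive by Th2), 43.67% (H3K4me1, naive by Th2), 75.6% (H3K4me1, KO), 88.59% (H3K27ac) and 60.15% (H3K4me1, both experiments). For higher genes near Th2 WT H3K9me3 peaks absent in KO, the odds ratio was 1.054 with peaks above the median score. Grouped by length it was 1.016, and both fell short of the threshold. Lower genes passed at 20 kb for H3K27ac (0.922) and H3K4me1 (0.841). For ATAC, where the main result had passed only before adjustment over the 10 tests, they missed it at 100 kb (0.933) and turned direction grouped by length (1.019). Lower naive genes near H3K9me3 peaks absent in KO passed grouped by length (1.293). All these alternatives were judged on p without adjustment over the tests. The cause was not tested. In a simulation of 200 changed genes limma recovered 74.6%, 76.6% and 60.7% of 2-fold changes in naive, Th2 and Th2-Th1 libraries. These shares rest on 63, 64 and 61 genes drawn from well-expressed ones, with all but the 200 genes unchanged. In the real Th2 comparison 9324 of 17254 genes were called, so the shares do not measure recovery there.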

Other observations

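The tests below on gene families, the X chromosome and active marks in H3K9me3 regions absent in KO were chosen after the result was seen. So were those on genes lower in all 3 conditions and the permutation within classes of gene length. Histone genes rose in 31 of 68 cases and fell in none in naive libraries labelled Setdb1 KO, with a median log2 change of 0.96 (0.94 with TMM scaling). Variable genes of the T cell receptor alpha chain rose in 19 of 64 cases in Th2 libraries labelled Setdb1 KO, with a median of 1.24. With reads thinned to equal depth the median was 0.92. Of all genes 5063 of 17254 were higher there, a similar share. From naive to Th2 WT cells 48 of the 64 variable genes fell. Ribosomal protein genes fell in 68 of 82 cases and rose in 6 in Th2 libraries labelled Setdb1 KO (median -1.81, and -1.68 with TMM scaling). In WT cells moved to Th1 conditions 62 fell and 8 rose (median -1.18). After the same move in cells labelled Setdb1 KO 2 fell and 13 rose (median 0.2). Between Th2-Th1 genotypes 39 fell and 8 rose (median -0.38). Ribosomal protein reads were 9.014 to 9.835% in Th2 WT libraries and at most 6.181% in any other, so the Th2 WT libraries stood apart. Of the Th2 WT H3K9me3 peaks 32 lay on the X chromosome, 0.26% of the list, against 0.38% in naive WT, 0.76% in Th2 Setdb1 KO, 1.01% in Th2 Suv39h1 KO, 1.89% in naive Setdb1 KO and 2431 (2.64%) of accessible regions in Th2 WT.

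Regions with an H3K9me3 peak in Th2 WT and none in the far shorter Setdb1 KO list could have gained active marks. Of 11694 Th2 WT H3K9me3 peaks absent in Setdb1 KO, 570 (4.87%) held an H3K27ac peak found in KO alone, against 0.89% at random, and 89 (0.76%) an H3K27ac peak found in WT alone, against 0.6%. The odds ratio of KO-only against WT-only H3K27ac peaks lying in these regions was 4.35 (Fisher's exact test, two-sided, p = 3.1e-52). In the 539 regions with an H3K9me3 peak in both lists it was 20.27, with only 6 WT-only peaks there. For H3K4me1 the odds ratio was 5.17 in the former and 15.29 in the latter regions, but for ATAC 7.37 and 4.3. The marks went both ways, so the gain could not be tied to the absence of H3K9me3.

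It was asked whether genes beside H3K9me3 regions absent in KO that held a KO-only H3K27ac peak could be higher more often. Of 844 such genes 272 (32.2%) were higher in Th2 libraries labelled Setdb1 KO, against 30.8% of other genes near regions absent in KO. This difference was not detectable here (odds ratio 1.066, Fisher's exact test, p = 0.412). Genes higher in all 3 conditions lay more often near regions with H3K9me3 in both WT lists and neither Setdb1 KO list: 146 of 318 (45.9%) against 35.7% of other genes. Grouped by gene length the odds ratio was 1.359 (permutation p = 0.00883), and for genes lower in all 3 it was 0.924 (p = 0.651). Grouped by length, lower genes of single conditions also lay more often near regions absent in KO. The odds ratio was 1.293 (permutation p = 0.00356) in naive and 1.261 in Th2 cells. Whether these regions silence nearby genes was therefore left open.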
